A study of Danio rerio with 4 samples.

How the data were processed

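Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an anti-myc antibody on chromatin from whole zebrafish embryos. Transgenic embryos carried a heat-shock-inducible, myc-tagged tbx6 gene (hsp70l promoter), and wild-type embryos carried no tagged protein. Per the labels' protocols, embryos were raised at 28.5 °C, heat-shocked for 1 h at 37 °C at the stage labelled 10S and fixed in 1.85% formaldehyde for 15 min. Libraries were amplified for 15 cycles and fragments of about 250 bp, adaptors included, were taken from a gel, per the labels' protocols. The series design lists 3 ChIP and 3 input libraries, of which 2 ChIP libraries came from transgenic and 1 from wild-type embryos. The labels describe 4 samples, and 2 of them, the transgenic and the wild-type ChIP, have a peak list. The input samples have no peak list of their own here.

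Reads were aligned with Bowtie to Zv9 (danRer7), per the submitters' processing notes. The Bowtie version, its handling of reads with several matches, the peak caller and its threshold are not given in the sources used here. Per the file headers, each peak has a chromosome, a start, a stop, a width and a score equal to 10 times the negative log10 of a p-value. For the transgenic list the score is an average, per the file headers, and the labels say that both ChIP libraries and both inputs were merged. All 3997 averaged scores were multiples of 0.005, and 49.2% of them ended in 5 thousandths. The wild-type list comes from 1 ChIP library, and 0% of its scores ended that way. Both ends of an interval are included, since stop minus start plus 1 equalled the stated width in all 3997 and all 398 rows. Positions were taken as 1-based, which this does not show. Both scores are the authors' own values, and were used only to describe and rank peaks within a list. The lists hold no read counts, fold enrichments, sequences or gene names, so the sequencing depth behind a peak is unknown. Depth changes how many peaks a caller reports and how high they score, so the number of peaks and the scores cannot be compared between the lists as binding levels.

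Each list stands for 1 sample and there are no replicate lists. The p-values below describe how the peaks of these lists lie or score, not a difference between conditions, and neighbouring peaks are not independent. A Tbx6myc peak was said to overlap the wild-type background where it shared at least 1 bp with a wild-type peak. The overlap and the spacing of the Tbx6myc peaks were set against 10000 random placements, in which each peak kept its width and its chromosome or scaffold (one-sided permutation test, smallest p 1e-04). The largest coordinate in either list stood in for the length of a sequence, so peaks on short scaffolds had little room to move and overlapped often by chance. Assembly gaps and unmappable stretches were not masked. Peaks counted as clustered where the nearest other peak lay within 10 kb, edge to edge. Scores were compared by a two-sided permutation test on the difference of medians with 100000 relabellings (smallest p 1e-05). Shares were compared with Fisher's exact test, and carry 95% Wilson intervals that cover counting error only. The 25 numbered chromosomes were compared by 10000 multinomial draws and by exact binomial tests with Benjamini-Hochberg adjustment. The chromosome tests, the comparison of unplaced shares and the overlap on scaffolds alone were chosen after the lists had been seen.

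Peaks were named by a rule set before the data were examined. It took the 10 strongest Tbx6myc peaks outside the wild-type peaks, the 5 strongest that overlapped one, the 5 strongest wild-type peaks and the 5 densest 50 kb windows, with ties broken by chromosome and position. No annotation or sequence of Zv9 was used here. The planned tests of peaks near transcription start sites, of T-box motifs and of gene lists fixed in advance (segmentation, myogenesis, signalling, other tissues, heat shock) therefore could not be made, and peaks are named by position rather than by gene. Alternatives covered the overlap rule, a stricter score threshold, the clustering distance and peaks on numbered chromosomes only. Local placements, the removal of chromosome 4 and the removal of 1 of each identical pair of Tbx6myc peaks were added after the lists had been seen. Identical peaks of the wild-type list were kept.

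The tests were run on simulated lists of 3997 peaks, with fewer placements and relabellings than the main tests. Peaks without a planted effect were drawn by the same uniform placement that the tests take as chance, and scores as independent values. The simulations therefore check the calculation, not how regional density or unmappable stretches affect the tests. Of 20 lists with no planted effect, 2 gave an overlap p under 0.05, 2 a clustering p and 0 a score p under 0.05. With 60 planted overlaps, 63 were found above the random mean. With 400 planted clustered peaks, 343 were found above it. Over 20 lists with a planted score ratio of 1.5, the mean estimate was 1.50 and 19 had p under 0.05. Overlaps from the fast search were the same as those from a direct search for all 3997 peaks. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.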

Results

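To map where induced, myc-tagged Tbx6 binds in the zebrafish genome, chromatin was precipitated with an anti-myc antibody from heat-shocked whole embryos carrying the transgene. Tbx6 is a T-box transcription factor of the presomitic mesoderm, the tissue from which somites, the precursors of vertebrae and skeletal muscle, are formed. The tagged protein was driven by a heat-shock promoter in whole embryos, so its peaks need not be sites of endogenous Tbx6. Wild-type embryos given the same heat shock and antibody served as the control, since they have no tagged protein. The transgenic list, which merges 2 ChIP libraries, held 3997 peaks covering 2.07 Mb. The wild-type list, from 1 ChIP library, held 398 peaks covering 0.366 Mb. There were no replicate lists, so no value below has an error between replicates, and the depth of the libraries is unknown. Scores are the authors' own, 10 times the negative log10 of a p-value, given as an average for the transgenic list, and positions are on Zv9.

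As deposited, Tbx6myc peaks were narrower than the wild-type peaks and lay mostly on the numbered chromosomes. Their median width was 484 bp (quartiles 394 and 596 bp), against 830.5 bp (593 and 1098 bp) for wild-type peaks, and 173 of them were narrower than the narrowest wild-type peak of 277 bp. In the Tbx6myc list, 50 peaks formed 25 pairs of identical width and score. Of the Tbx6myc peaks, 3788 lay on the 25 numbered chromosomes and 209 on 129 unplaced scaffolds. The unplaced share was 5.23% (95% interval 4.58 to 5.96%). In the wild-type list, 158 of 398 peaks lay on 80 unplaced scaffolds, a share of 39.7% (35.0 to 44.6%). The odds of an unplaced position were 11.9 times higher for wild-type than for Tbx6myc peaks (Fisher's exact test across peaks, two-sided p = 6.5e-78). This test takes peaks as independent although many shared a scaffold, so its p-value can be too small. Placed peaks numbered 3788 and 240, so the ratio also depends on how many of them were called at an unknown depth. Scores had a median of 190 in the Tbx6myc list, with a range from 93.7 to 2177. In the wild-type list the median was 111, with a range from 93.1 to 516.

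The wild-type control asks which peaks of the transgenic embryos also appear without a tagged protein. Of the 3997 Tbx6myc peaks, 44, or 1.1% (95% interval 0.821 to 1.47%), shared at least 1 bp with a wild-type peak. They met 42 of the 398 wild-type peaks, or 10.6% (7.90 to 13.96%). The overlap exceeded random placement of the Tbx6myc peaks, which gave 20.5 overlaps on average and 36 at most (one-sided permutation test, p = 1e-04, the smallest that 10000 placements can give). Of the 44 overlapping peaks, 34 were on unplaced scaffolds, 1.73 times the 19.7 that random placement gave there on average (permutation test, p = 1e-04). On numbered chromosomes alone, 10 peaks overlapped, 11.4 times the random mean of 0.874 (permutation test, p = 1e-04). Among these 10 were both members of an identical pair on chromosome 16, at 11041988 and 11176842, which may count 1 signal more than once. With at least 50% of both peaks shared, 30 peaks overlapped, against a random mean of 5.73. A further 58 of the 175 unplaced peaks without an overlap lay on a scaffold that also held a wild-type peak.

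Over all sequences together, Tbx6myc peaks that overlapped the wild-type background scored higher than the others. Their median score was 287 (quartiles 205 and 402, 44 peaks), against 189 (143 and 283) for the other 3953 peaks, a difference of 98.1 (two-sided permutation test across peaks, p = 1e-04). The groups also differed in location, with 77.3% of the overlapping peaks on unplaced scaffolds against 4.43% of the others. Neither location nor peak width was matched, so the difference cannot be assigned to the overlap itself. On numbered chromosomes alone the medians were 266 for 10 overlapping peaks and 189 for the rest, and the difference of 77.2 did not pass the threshold (permutation test, p = 0.063). These 10 peaks include both members of the identical pair on chromosome 16. The strongest overlapping peak was a 1372 bp interval at 21721 to 23092 of scaffold Zv9_NA496, with an averaged score of 1060, over a wild-type peak at 21733 to 23173 that scored 218. The next were at 41401 to 42000 of Zv9_NA721 (score 808), 959 to 1426 of Zv9_NA408 (score 778) and 1371 to 1756 of Zv9_NA45 (score 634). The strongest on a placed sequence among the 5 was at 40106458 to 40107389 of chromosome 17, with a score of 536, over a wild-type peak that scored 153.

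**Figure D1:**
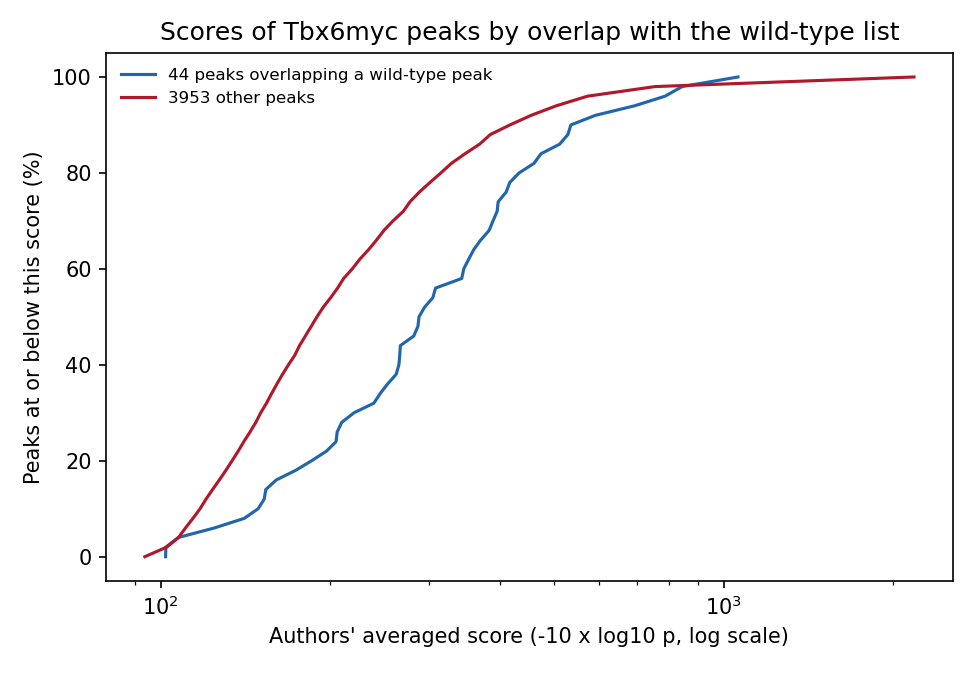
Cumulative percentage of Tbx6myc peaks (vertical axis) at or below each averaged score (horizontal axis, 10 times the negative log10 of p, log scale), for the 44 peaks that overlap a wild-type peak (blue) and the 3953 others (red). The blue curve lies to the right at the medians, 287 against 189, while the highest score, 2177, belongs to a peak outside the wild-type list.

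The 5 strongest wild-type peaks were broad, and 4 of them met no Tbx6myc peak. The highest score, 516, was at 1090 to 2642 of scaffold Zv9_NA371. A 5266 bp interval at 3889 to 9154 of Zv9_NA648 scored 458 and overlapped a Tbx6myc peak at 4163 to 9203 with a score of 266. The others were at 58250 to 59726 of Zv9_NA219 (score 457), 14138457 to 14140213 of chromosome 2 (score 450) and 12341918 to 12343401 of chromosome 24 (score 436).

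The strongest Tbx6myc peaks outside the wild-type list lay on 8 chromosomes. The peak with the highest score, 2177, spanned 35391815 to 35392640 of chromosome 2, and a second peak of score 503 lay 20.6 kb away at 35413215 to 35413864. The second strongest, at 23525754 to 23526413 of chromosome 23, scored 1686 and had 5 other peaks within 50 kb. Chromosome 10 held the third, at 10851737 to 10852520 with a score of 1463 and 5 other peaks within 50 kb. It also held the fourth, at 8709546 to 8710395 with a score of 1372, whose nearest neighbour was 537 kb away. The fifth was at 26015496 to 26016248 of chromosome 5 (score 1354). Next came 27628958 to 27630434 of chromosome 2 (score 1245) and 49307915 to 49308803 of chromosome 16 (score 1224). The last 3 were at 10645842 to 10647378 of chromosome 4 (score 1197), 30807807 to 30808352 of chromosome 7 (score 1177) and 6698521 to 6699139 of chromosome 11 (score 1164). Of these 10 peaks, 6 had another Tbx6myc peak within 10 kb and 8 had one within 50 kb. The nearest wild-type peak to any of the 10 was 468 kb away, from the peak on chromosome 16.

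Tbx6myc peaks lay in groups along the genome. Of the 3953 peaks outside the wild-type list, 1089 (27.5%) had another Tbx6myc peak within 10 kb, 3.88 times the mean of 280 in random placements, whose highest value was 358 (one-sided permutation test, p = 1e-04, the smallest possible). Joining peaks within 10 kb gave 3336 loci, of which 2864 held a single peak, 365 held 2 peaks, 81 held 3 peaks and 26 held more. At 0.5 kb, 3.62% of the peaks had a neighbour (random mean 0.949%), and at 1 kb 5.24% (1.35%). No minimum spacing was required, so pieces of 1 enriched region would count as neighbours. When each peak was moved only within 500 kb of its own position, the random mean rose to 408 and the ratio was 2.67 (permutation test, p = 1e-04). This keeps density differences over stretches much longer than 500 kb, but not over shorter ones.

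**Figure D2:**
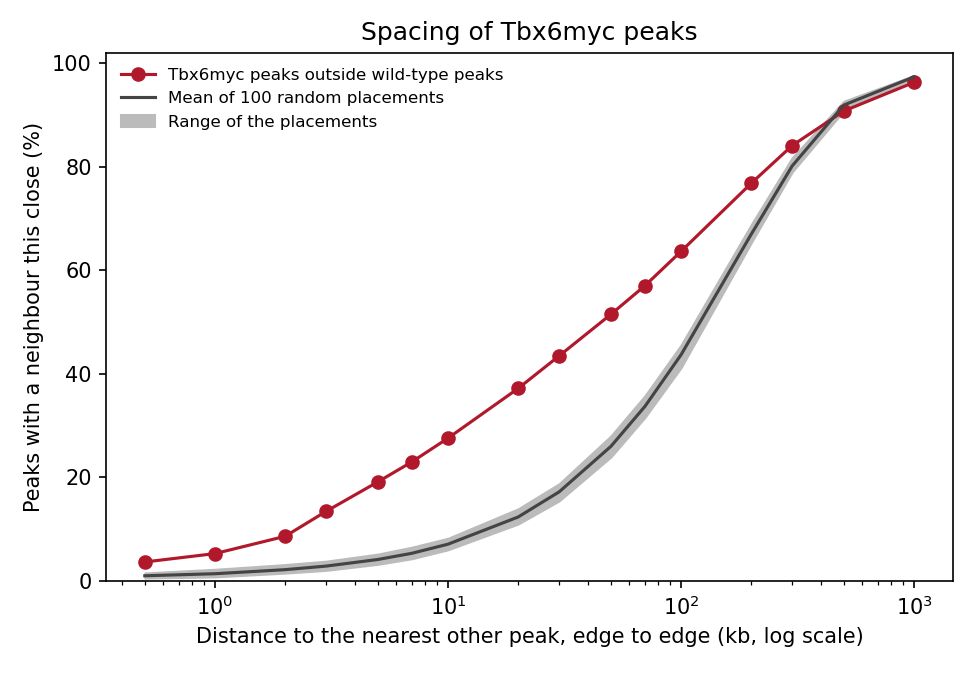
Percentage of Tbx6myc peaks outside the wild-type list (vertical axis) whose nearest other peak lies within the distance on the horizontal axis (kb, edge to edge, log scale). Red points are the observed peaks, the black line is the mean of 100 random placements and grey their range. At 10 kb the observed share is 27.5% against a random mean of 7.05%, and at 500 kb it lies at or below the placements, 90.8% against 91.9%.

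The densest window of 50 kb held 8 Tbx6myc peaks. It ran over 40.5 kb of chromosome 18, from 35643551 to 35684012, with scores from 99.0 to 846 and the strongest peak starting at 35678045. Chromosome 21 held 7 peaks in 27.6 kb from 36933621 to 36961218, with scores from 109 to 658. Chromosome 4 held 2 windows of 6 peaks. The first, from 10565880 to 10601749, reached a score of 756 and lay at lower coordinates than the peak of score 1197. The second, from 13429949 to 13454262, reached 357. Another window of 6 peaks was at 36197621 to 36219245 of chromosome 7, with a highest score of 565. In all, 11 non-overlapping windows held 6 peaks or more. In 1000 random placements the densest window of the genome held 5 peaks at the median and 6 at most.

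The numbered chromosomes differed in the density of Tbx6myc peaks. The 3778 peaks outside the wild-type list made a mean of 2.82 peaks per Mb, from 2.31 on chromosome 2 and chromosome 25 to 3.70 on chromosome 13, and the counts departed from chromosome length (10000 multinomial draws, permutation p = 1e-04, the smallest possible). Singly, chromosome 13 (200 peaks, 152 expected, adjusted p = 0.0035) and chromosome 11 (170 peaks, 131 expected, adjusted p = 0.010) were above their length's share by an exact binomial test with Benjamini-Hochberg adjustment over 25 chromosomes. No chromosome passed the test below its share. Chromosome 4 held 147 of these peaks, 143 before its midpoint at 30.6 Mb and 4 beyond it. The part beyond the midpoint thus held 2.72% of the peaks (95% interval 1.06 to 6.79%, exact binomial test, adjusted p = 5.4e-36). On the 24 other chromosomes the part beyond the midpoint held between 39.3 and 66.7%. Chromosomes 12, 14 and 23 had more peaks beyond the midpoint (66.7%, 65.3% and 65.4%, adjusted p = 0.0017, 0.0017 and 0.0016 by the same exact test). All these tests take peaks as independent, although the peaks lay in groups, so their p-values can be too small.

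Between neighbouring Tbx6myc peaks outside the wild-type list, the longest stretch was 13.3 Mb and lay on chromosome 4, from 27923605 to 41265263. The longest between neighbouring peaks on any other chromosome was 5.50 Mb, on chromosome 7. Stretches before the first or beyond the last peak of a chromosome were not measured. Chromosome 4 had no such peak in the 5 Mb bins that start at 50, 55 and 60 Mb. Wild-type peaks did not follow the Tbx6myc peaks on chromosome 4: 10 of its 17 wild-type peaks lay beyond the midpoint, against 4 of all 149 Tbx6myc peaks, those that overlap a wild-type peak included (Fisher's exact test, two-sided p = 5e-09).

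**Figure D3:**
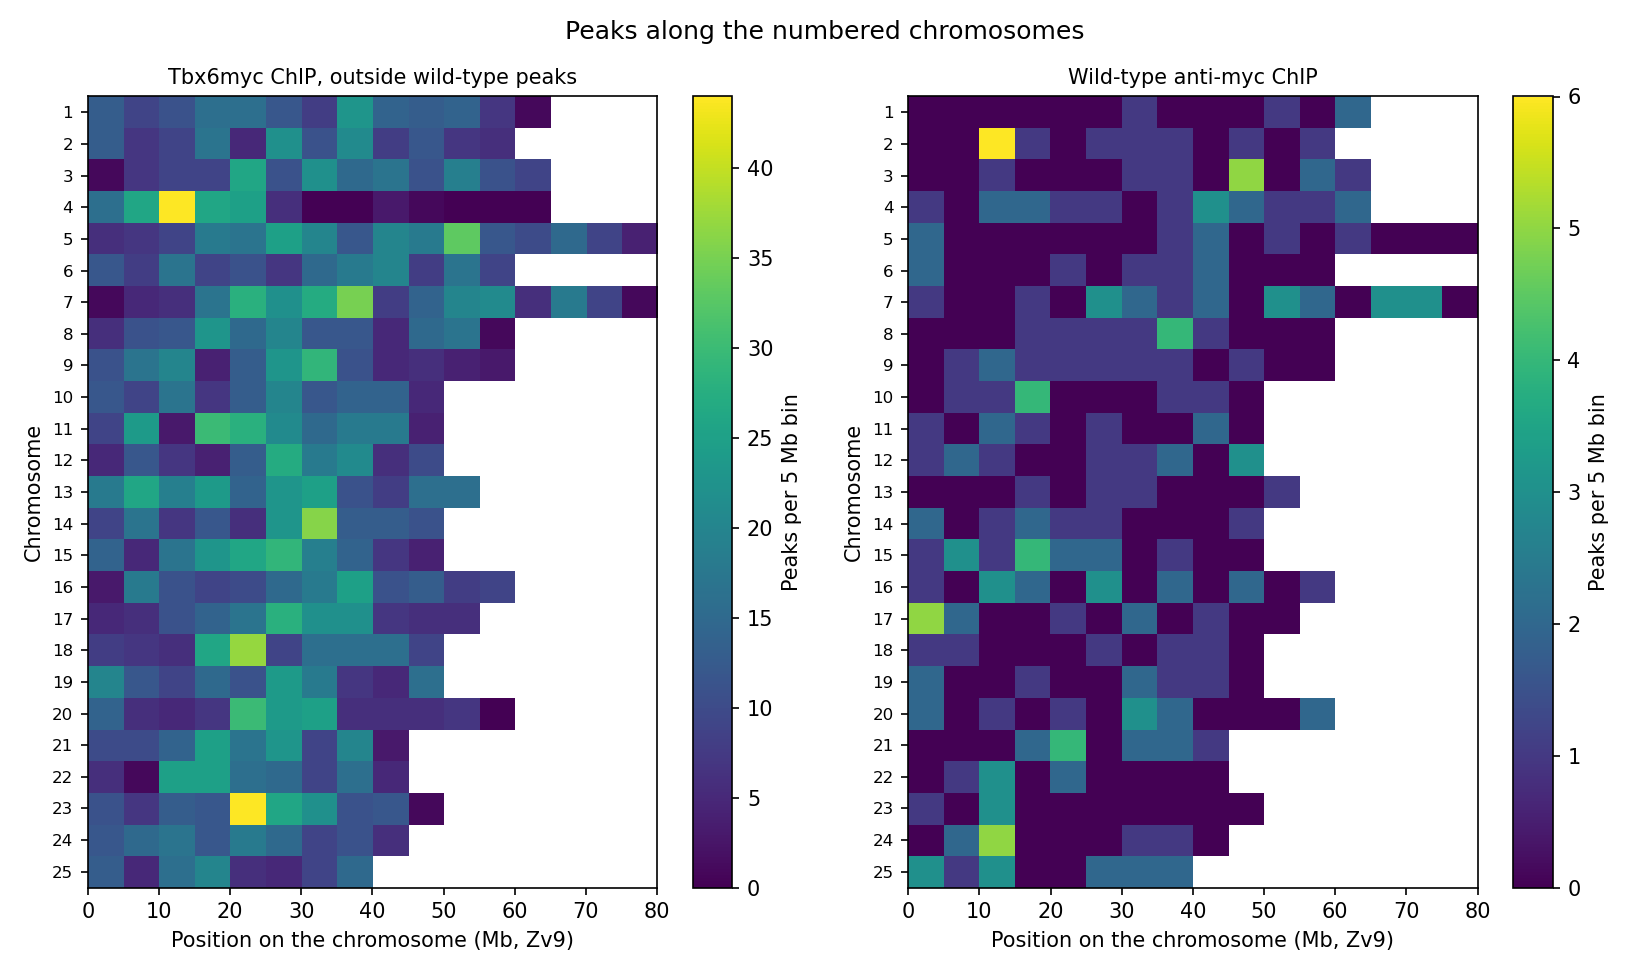
Number of peaks per 5 Mb bin (colour, one scale per panel) along the 25 numbered chromosomes (rows) by position in Mb on Zv9 (horizontal axis), for Tbx6myc peaks outside the wild-type list (left) and wild-type peaks (right). The last bin of each chromosome is shorter than 5 Mb. On chromosome 4 the bin at 10 Mb holds 44 Tbx6myc peaks, while the bins from 30 Mb on hold 4 in all, beside 10 wild-type peaks.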

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

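Each of the 18 alternatives run kept the direction of its result. For the overlap of the lists, 6 of 7 alternatives stayed within 1.5 times the 44 overlapping peaks, from 30 peaks when 50% of both peaks had to be shared to 46 with midpoints within 1 kb. With the 50% rule the excess over random rose to 5.24 times (5.73 expected), and the other 5 gave 2.10 to 2.44 times. Of these 5, placement within 500 kb was nearly the main test again, with 20.6 overlaps expected against 20.5. Most overlapping peaks, 34 of the 44, were on scaffolds, where peaks had little room to move in either test. On numbered chromosomes only, the count was 10 peaks, 11.4 times the random mean of 0.874, against 2.14 times over all sequences, since the scaffolds, where chance overlap is high, are left out. For the score difference, the median of overlapping peaks was 266 on numbered chromosomes only (p = 0.063 by permutation), which no longer passed the threshold with 10 overlapping peaks left. The other alternatives gave 286 and 287 with p of 0.0011 and 1.9e-04. For clustering, the count was 2035 peaks at 50 kb (1.99 times the random mean) and 423 among the peaks at or above the median score (5.26 times). Both counts change by construction, while each ratio is against random placements under the same setting. The other 6 gave 755 to 1126 peaks, at ratios from 2.67 to 4.68. Chromosome 4 did not carry the clustering, with 1042 peaks and a ratio of 3.81 without it. Another score column does not exist in the lists, so that alternative was not run, nor were those of the start-site, motif and gene-list tests. No paired analysis was possible because each group has 1 sample. Depth is unknown, so a wild-type signal under the caller's threshold at a Tbx6myc peak would not be seen, and the 1.1% overlap is a share of called peaks only.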

Other observations

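All tests in this part were chosen after the result they bear on had been seen. Peaks in groups scored higher than isolated peaks. The 1089 Tbx6myc peaks with a neighbour within 10 kb had a median score of 213, against 182 for the 2864 isolated peaks, a difference of 31.1 (two-sided permutation test across peaks, p = 1e-05, the smallest that 100000 relabellings can give). Their median width was 511 bp, against 474 bp (permutation test, p = 1e-05).

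In the Tbx6myc list, 50 peaks formed 25 pairs with exactly the same width and exactly the same averaged score. Shuffling the widths over the scores left 0.670 such peaks on average and 8 at most in 1000 shuffles. Of the 25 pairs, 22 (88%) lay on 1 chromosome, at a median distance of 132 kb, where 10000 random pairings put 0.906 pairs on 1 sequence on average and 6 at most, which argues against ties of width and score by chance. That the pairs are reads placed in near-identical copies of the sequence is a candidate explanation, which predicts that neighbouring pairs keep their spacing. The 2 sets of pairs with members within 10 kb of each other kept it within 10 bp, but they cover 4 of the 25 pairs and the sequences were not compared, so the explanation stays open for the rest. On chromosome 16 the pair at 11041988 and 11176842, 134854 bp apart, met a pair of wild-type peaks the same 134854 bp apart.

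On chromosome 25, peaks starting at 35202793 and 35205656 had their twins at 35230394 and 35233257, both 27601 bp away. On chromosome 14, peaks starting at 34981277 and 34985255 had theirs in mirrored order at 35067061 and 35062912, with a mirrored spacing that differed by 4 bp. The strongest pair, at 37580390 and 37644372 of chromosome 10, scored 892 at both positions. With 1 of each pair dropped, 3972 Tbx6myc peaks are left. The wild-type list held 62 such peaks, in 28 pairs and 2 triplets, where shuffling the widths left 0.786 on average and 8 at most. Of its 28 pairs, 1 lay on 1 sequence, where random pairing gave 0.522 on average (one-sided permutation test, p = 0.41). Among the 79 pairs of wild-type peaks of equal width, 34 also had equal scores, against 25 of 14930 in the Tbx6myc list. The 1 set of neighbouring wild-type pairs, on chromosomes 21 and 7, had a spacing of 1720 bp on both. The origin of the other wild-type ties was not tested.

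Beyond its midpoint, chromosome 4 held 4 of its 147 Tbx6myc peaks outside the wild-type list, and 4 of all 149. A complete lack of placeable reads there is argued against by 10 wild-type peaks in the same part, although reads of repeats alone could give such peaks and poorer mappability of single sites stays open. A general fall of peaks towards the far ends is argued against by the other 24 chromosomes, whose lowest share beyond the midpoint was 39.3%. The long arm of this chromosome is known as heterochromatic and rich in repeats, and a lack of accessible sites there is a biological hypothesis that these lists do not test. Chromatin accessibility and mappability measured along that arm would bear on it.

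The Tbx6myc list held 173 peaks (4.33%) narrower than the narrowest wild-type peak of 277 bp, among them 13 under 100 bp and a narrowest interval of 6 bp. A candidate explanation is that each deposited interval is the stretch shared by a peak of both libraries. It was drawn from the 173 narrow intervals themselves, so they do not test it. Sharper peaks at true sites could also lower the median width to 484 bp. The 2 explanations cannot be told apart, since the peaks of the single libraries were not used here.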
